A study of Mus musculus with 4 samples.

How the data were processed

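The data were read counts of single nuclei sorted from the hippocampus of adult mice and sequenced by Smart-seq2, a plate method that copies full-length RNA of 1 nucleus per well and carries no molecular identifiers. There were 4 libraries, 1 in each of 4 groups: NeuN+ WT, NeuN+ Fasn-R1812W, EdU+ WT and EdU+ Fasn-R1812W. The deposited values were counts of reads per gene and well, whole numbers with different totals per well and no normalization. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.3a to mouse build GRCm38.p5. The counting program, its annotation and its strand setting are not given in the sources used here. Reads of a gene and of a partner on the opposite strand could therefore not be told apart, and genes with close copies may share reads. Each table held 25567 genes and 384 wells, whereas 382 nuclei were stated per library, and no label says which wells held no nucleus. A symbol was found for 25395 genes by matching identifiers, and positions were taken from an annotation of the same build, GENCODE release M21. Embryonic nuclei named in the series design were not analysed here.

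Total counts per library were 71221156, 72468235, 36368990 and 96597804 in the order of the groups above. Nuclei with a read in at least 1000 genes and at least 50000 reads were kept, which left 314, 301, 167 and 348. Counts were summed over the kept nuclei of a library and divided by the total of nuclear-encoded genes to give CPM, the reads of a gene per 1e6 reads of the library. Log2 ratios of Fasn-R1812W over WT were taken after adding a prior of 1 CPM, which pulls the ratios of low genes toward 0. Genes with a pooled CPM of at least 10 and a read in at least 10% of nuclei in either library of a pair entered the counts of genes at least 2-fold apart. Since there was 1 library per group, genotype could not be tested within a gate; a joint fit of gate and genotype over the 4 libraries was not run, and no p-value was computed. Intervals of counts are exact Poisson and those of shares exact Clopper-Pearson at 95%, and intervals of share differences follow Newcombe. A gene with no read was set at the limit of 3 reads that a count of 0 allows. All such intervals and limits cover counting error only, since reads copied by PCR are not independent molecules, and they say nothing about the spread between animals.

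The median log2 ratio of each of 29 gene lists and 22 cell type marker lists was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Members needed a pooled CPM of at least 5, and a list stood apart when its percentile was under 2.5 or over 97.5. Nuclei of each gate were clustered with scanpy 1.11.5 on log-transformed counts per nucleus, with 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering from igraph 0.11.9 at resolution 1. Sex-linked and mitochondrially encoded genes were left out, and no batch correction was made because library and genotype coincide. A cluster took the name of the marker list with the highest mean log2 fold when at least 3 of its markers were at least 2-fold up and its 10 leading genes held no more markers of another type than of its own. A cluster with Ptprc at least 2-fold up that did not score highest for microglia was called a leukocyte-gene cluster. The clustering of all 4 libraries together that had been foreseen for the gate comparison was not made, and that comparison rests on pooled counts. No doublet caller was run; leaving out the 5% of nuclei with the most genes served as an alternative. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, with scaling factors from edgeR 4.0.16 in R 4.3.3 as an alternative.

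The groups, gene lists, markers, nucleus filter, gene filters and rule for named genes were fixed before the data were examined. The rule for naming clusters, the leukocyte-gene class and the relaxed nucleus filter of at least 300 genes and 20000 reads were set afterwards. Named genes needed 20 CPM, a read in at least 10% of nuclei and no nucleus with over 20% of the reads in the higher library. Pooled CPM, mean CPM per nucleus and the share of thinned nuclei with a read also had to go the same way. Predicted genes, clone names, pseudogenes and mitochondrially encoded genes were left out. The 12 genes with the largest ratio in each direction are named, along with Fasn, Y-linked genes and up to 4 members of each list. Alternatives fixed beforehand were the mean CPM per nucleus, edgeR's TMM scaling, a strict nucleus filter of 2000 genes and 100000 reads, no nucleus filter, thinning every nucleus to 69000 reads, other gene filters, a prior of 0.1 CPM and other clustering settings. The ratio step was tested on simulated counts over 25567 genes. For each fold of 4, 2, 0.5 or 0.25, at least 49 of 50 altered genes came out in the right direction in both gates. Both simulated libraries were drawn from the WT nuclei of a gate. They therefore lacked the differences in genes per well and class make-up of the real pairs. Unchanged genes that came out 2-fold apart were not counted, so the test does not bear on the counts of such genes.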

Results

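Transcripts of single hippocampal nuclei were compared between wild-type (WT) mice and Fasn-R1812W mice, which carry a substitution in fatty acid synthase, the enzyme that builds palmitate. Nuclei came from animals aged 8.5 months and were sorted in either of 2 ways. The NeuN+ gate took nuclei stained for the neuronal protein NeuN. The EdU+ gate took nuclei that had built the thymidine analogue EdU into their DNA. It was given at 100 mg per kg, 2 times a day for 3 days, and nuclei were isolated on day 4. Each gate and genotype had 1 library of 384 wells, so every difference between genotypes is a difference between 2 libraries with no replicate check.

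Genes per well were similar in the NeuN+ pair and very different in the EdU+ pair. The median well held 188610 reads in NeuN+ WT and 116979 in NeuN+ Fasn-R1812W, with 4260 and 4271 genes detected. In EdU+ WT the median well held 964 genes, against 2911.5 in EdU+ Fasn-R1812W, from medians of 85405.5 and 204218 reads per well and 36368990 and 96597804 reads in total. Total reads were 71221156 in NeuN+ WT and 72468235 in NeuN+ Fasn-R1812W. The filter of at least 1000 genes removed 199 of 384 EdU+ WT wells and 0 of 384 EdU+ Fasn-R1812W wells. Because of that imbalance, many EdU+ values are given with those of a relaxed filter, which kept 352 WT and 376 Fasn-R1812W nuclei.

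**Figure D1:**
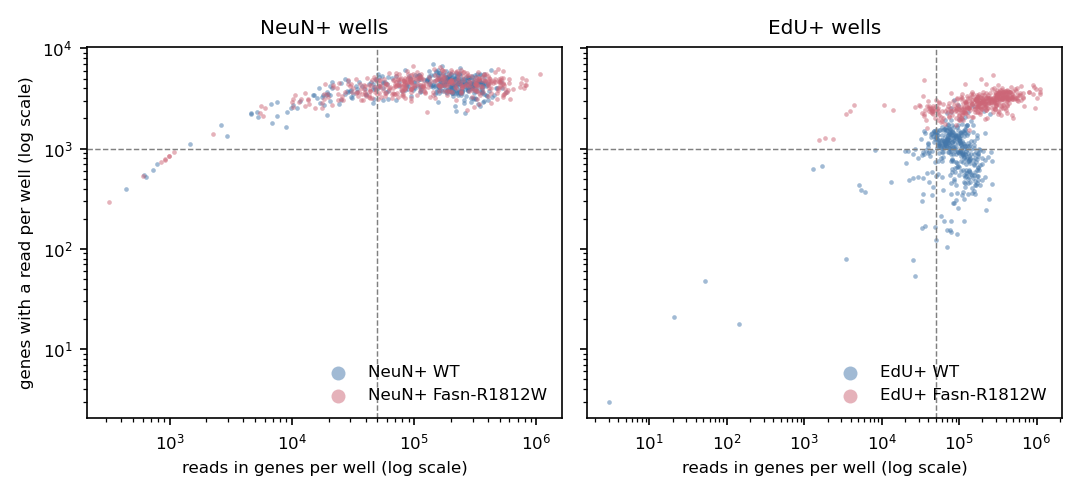
Each point is 1 well, with reads in genes on the x axis and genes with a read on the y axis, both on log scales, and dashed lines at the minimum of 50000 reads and 1000 genes. NeuN+ wells of both genotypes overlap, while EdU+ WT wells sit below EdU+ Fasn-R1812W wells, with medians of 964 and 2911.5 genes.

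Transcripts of Fasn itself were present in all 4 libraries. Fasn (ENSMUSG00000025153) lies on the minus strand of chromosome 11 at positions 120805846 to 120824547 of GRCm38. NeuN+ nuclei held 35.3 CPM (95% interval 33.9 to 36.8) in WT and 31.7 CPM (30.4 to 33.0) in Fasn-R1812W, a log2 ratio of -0.15. EdU+ nuclei held 167 CPM (161 to 174) in WT and 104 CPM (102 to 106) in Fasn-R1812W, a ratio of -0.68 that came to 0.077 under the relaxed filter and to 6.77 under the strict filter, which left 5 EdU+ WT nuclei. A single nucleus held 25.5% of the Fasn reads in EdU+ WT and 27.2% in NeuN+ Fasn-R1812W. Within oligodendrocyte precursor-like EdU+ nuclei the values were 211 and 199.8 CPM. Within NeuN+ classes Fasn stood at 35.5 and 40.7 CPM in granule-like, 27.3 and 33.6 CPM in CA1-like, and 41.8 and 16.5 CPM in interneuron-like nuclei, whose clusters differed in make-up between the libraries. A substitution need not alter transcript level, and single bases are not held in count tables, so the genotype labels were not tested by these values. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in every library, at 64.3 to 271 CPM in NeuN+ WT, 67.3 to 240 CPM in NeuN+ Fasn-R1812W, 70.4 to 203 CPM in EdU+ WT and 79.98 to 202 CPM in EdU+ Fasn-R1812W.

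The 2 gates held different cells in both genotypes. Genes of oligodendrocyte precursors were far higher in EdU+ than in NeuN+ nuclei, with median log2 ratios of 6.86 in WT and 6.07 in Fasn-R1812W. Pdgfra, the receptor that marks these precursors, reached 2275 CPM in EdU+ WT and 1672 CPM in EdU+ Fasn-R1812W, and Vcan 1759 and 1346 CPM. Markers of committed precursors were higher by 5.34 and 4.78, microglial markers by 5.15 and 4.88, and genes of the G2/M phase by 2.76 and 2.41. Mki67, the proliferation marker, stood at 143 and 106 CPM in EdU+ nuclei and at 24.1 and 33.4 CPM in NeuN+ nuclei. Top2a, a topoisomerase of dividing cells, stood at 98.3 and 51.3 CPM in EdU+ nuclei and at 0.201 and 0.171 CPM in NeuN+ nuclei. Neuronal markers ran the other way, with medians of -2.51 and -2.74. Syt1, the calcium sensor of synaptic vesicles, had 1773 and 1737 CPM in NeuN+ nuclei and 204 and 60.4 CPM in EdU+ nuclei, and Snap25 had 1785 and 1577 against 603 and 480 CPM. The examples are the 2 most abundant members of their lists in the WT library of the higher gate, a rule chosen after the values were seen.

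Among NeuN+ nuclei the question was whether the make-up and transcripts of neurons differed between genotypes. Dentate granule neuron-like nuclei were a smaller share of the Fasn-R1812W library, at 79 of 301 or 26.2% (95% interval 21.4 to 31.6), than of the WT library, at 133 of 314 or 42.4% (36.8 to 48.0). The difference was -16.1 percentage points (-23.3 to -8.62). Of its 3 clusters, the one led by C1ql2 and Prox1 held 48 WT and 19 Fasn-R1812W nuclei, the one with Il1rap and Dsp 35 and 18, and the one with Dock10 50 and 42. CA1 pyramidal neuron-like nuclei made up 16.6% in WT and 26.2% in Fasn-R1812W, a difference of 9.69 points (3.21 to 16.1), whose interval held 0 in 5 of 13 alternatives. CA3 pyramidal neuron-like nuclei made up 3.50% and 9.30%, though assigning each nucleus by marker score gave a difference of -0.0984 points. Subicular or entorhinal neuron-like nuclei took 3.18% and 5.98%, and GABAergic interneuron-like nuclei 14.6% and 14.0%, with intervals of the difference that held 0. The subicular difference was -1.17 points with the strict filter and had an interval above 0 in 6 of 12 alternatives, such as 6.03 points (1.48 to 10.8) in thinned nuclei. The interneuron difference of -0.696 points was positive in all 13 alternatives, at 0.260 to 4.42. The interneuron-like cluster led by Cnr1 and Adarb2 held 22 WT and 12 Fasn-R1812W nuclei, the one with Pvalb and astrocyte genes 12 and 21, and the one led by Sst and Npy 12 and 9, so the class held them in different proportions. Clusters without a name took 19.7% and 18.3%. Intervals cover the number of nuclei counted and not the dissection or the animal.

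**Figure D2:**
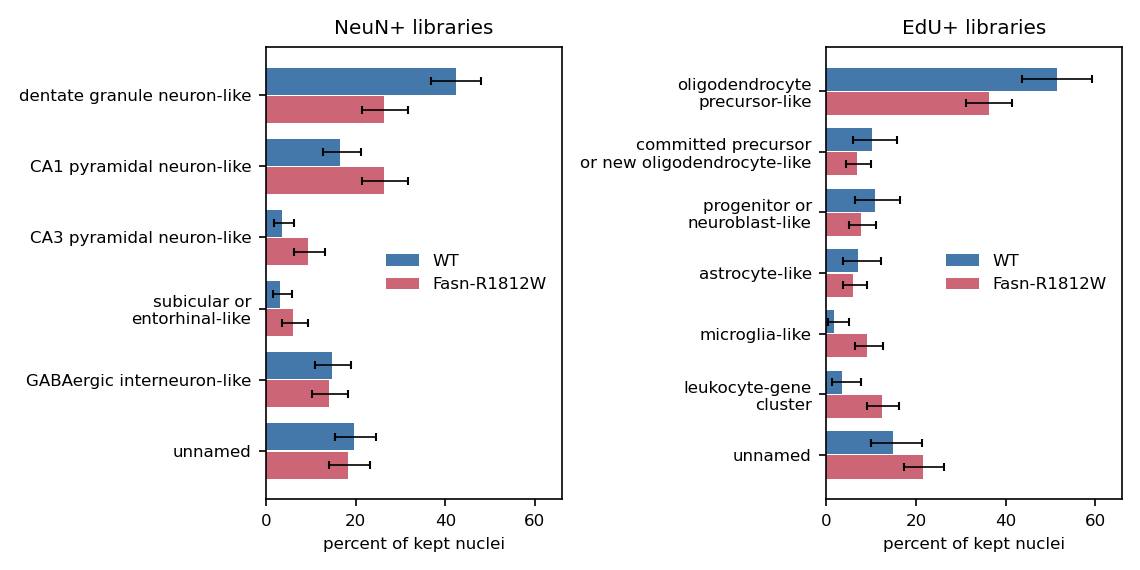
Bars show the percent of kept nuclei in each class for WT and Fasn-R1812W libraries, NeuN+ on the left and EdU+ on the right, with 95% exact Clopper-Pearson intervals for counting error. Granule neuron-like nuclei make up 42.4% of the NeuN+ WT and 26.2% of the NeuN+ Fasn-R1812W library.

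Of 16 cell type marker lists with enough members, 8 stood apart in the NeuN+ comparison. Granule neuron markers had a median log2 ratio of -0.78 and were lower in 8 of 9 members. Among them Dsp, which encodes desmoplakin, stood at 72.7 CPM in WT and 21.5 CPM in Fasn-R1812W, and Prox1, the transcription factor of granule neuron identity, at 255 and 125 CPM. Interneuron markers had a median of 0.46, with Lamp5 at 47.9 and 143 CPM, while Adarb2 went the other way at 205 and 126 CPM. Mossy neuron markers had a median of 0.84 over 4 members. Genes of cells that the gate should leave out also differed. Astrocyte markers were lower in 12 of 12 members (median -1.01) and ependymal markers in 4 of 4 (-2.32). Mature oligodendrocyte markers were higher in 11 of 11 (0.80), oligodendrocyte precursor markers in 4 of 6 (1.34) and microglial markers in 6 of 7 (1.78). At least 3 markers of a glial type at 100 CPM or more were found in 46 of 314 WT and 41 of 301 Fasn-R1812W nuclei. Wells were also thinned to equal depth and searched for at least 3 markers of a type with at least 3 reads each. Astrocyte markers were found in 40 of 350 WT and 31 of 352 Fasn-R1812W wells, and mature oligodendrocyte markers in 5 and 7. Oligodendrocyte precursor and microglial markers were each found in 1 and 2 wells, and ependymal markers in 1 and 0. The precursor, microglial and ependymal medians may therefore rest on very few nuclei.

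Of the 29 gene lists, 6 stood apart in the NeuN+ comparison. Genes of phospholipid and sphingolipid synthesis had a median of 0.30 and were higher in 13 of 19 members, with 0.40 within CA1-like, -0.036 within granule-like and -0.029 within interneuron-like nuclei. Sptlc1, a subunit of the enzyme that starts sphingolipid synthesis, stood at 51.5 and 88.4 CPM, while Chpt1 of phosphatidylcholine synthesis was lower at 135 and 82.5 CPM. Glycolytic genes had a median of 0.22, higher in 14 of 18, with 0.30 within granule-like, 0.24 within CA1-like and 0.18 within interneuron-like nuclei. Pkm, or pyruvate kinase, stood at 337 and 493 CPM and Gpi1 at 371 and 528 CPM. Aldoc, which is also an astrocyte marker, was lower at 117 and 67.7 CPM. Mitochondrially encoded transcripts were lower in 9 of 9 members with a median of -0.78, and mt-Nd5 stood at 187 and 98.1 CPM. Within classes their median was -0.41 in granule-like, -0.62 in interneuron-like and 0.31 in CA1-like nuclei. Such reads were 0.24% of all reads in NeuN+ WT and 0.16% in NeuN+ Fasn-R1812W, and their source in sorted nuclei was not tested. Genes of G1/S and DNA replication had a median of -0.60, lower in 12 of 17, with Pcna at 43.1 and 27.3 CPM. Within classes that list did not stand apart, with -0.27 in granule-like, 0.064 in CA1-like and 0.45 in interneuron-like nuclei. Neurogenesis transcription factors had a median of -0.33, lower in 12 of 15. The 4 that were at least 2-fold lower included Tbr1 with a ratio of -1.13 and Prox1, which is also a granule neuron marker. Their medians within granule-like, CA1-like and interneuron-like nuclei were -0.23, -0.33 and -1.29, and only the last stood apart. Granule neuron markers had -1.51 in that interneuron-like class, whose clusters differed in make-up between the libraries. Cytosolic ribosomal protein genes had a median of -0.20, lower in 17 of 22, with Rps6 at 112 and 75.2 CPM; many have processed copies that can share reads. Within granule-like, CA1-like and interneuron-like nuclei they had -0.22, -0.034 and -0.041.

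Lipid lists closest to the enzyme did not stand apart in the whole NeuN+ comparison. Fatty acid synthesis had a median of -0.18 at percentile 9.54, cholesterol synthesis 0.032, fatty acid oxidation -0.18 and lipid droplet turnover -0.11. Within CA1-like nuclei fatty acid oxidation stood apart with -0.74. It did not stand apart within granule-like nuclei, at 0.20, or within interneuron-like nuclei, at -0.45. Many lists were placed in each class with no correction for their number, so a single list standing apart in a class carries little weight. Synaptic lists did not stand apart in the whole NeuN+ comparison either. They had -0.051 for glutamatergic synapse, -0.10 for GABAergic synapse and 0.14 (percentile 96.7) for presynaptic vesicle release genes. Within interneuron-like nuclei GABAergic synapse genes stood apart with 0.54, as did interneuron markers with 0.50 and astrocyte markers with -5.46. That class held its clusters in different proportions in the 2 libraries and astrocyte transcripts in unequal amounts, so these values cannot be read as changes within interneurons. The proportions do not give the direction of the astrocyte value, as the cluster led by astrocyte genes held 12 WT and 21 Fasn-R1812W nuclei. The source of the astrocyte transcripts was not tested. Immediate early genes, which follow neuronal activity, had a median of -0.014.

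Single genes at least 2-fold apart were balanced in NeuN+ nuclei, with 345 higher and 330 lower in Fasn-R1812W among 10895 genes. Col6a4, a collagen VI chain on chromosome 9 at 105989454 to 106096783, stood highest. Its 3.84 CPM (3.40 to 4.33) in WT compared with 32.0 CPM (30.7 to 33.4) in Fasn-R1812W, a log2 ratio of 2.77. Next came Mknk2, a kinase that phosphorylates eIF4E, at 2.22, and Srgap1 at 1.94. Pex11g, a factor of peroxisome division, had 1.86, Itga6, an integrin subunit, 1.86, and Urod of haem synthesis 1.81. Kctd5 at 1.77, Cfap100 at 1.76, Arhgdig at 1.76, Trpc5os at 1.75, Ephb2 at 1.66 and Nudt16l1 at 1.62 completed the set. Trpc5os is named as an opposite-strand transcript of Trpc5, so its reads are uncertain without strand. In the other direction Pcdhb9 had a ratio of -2.66, with 24.7 and 3.05 CPM, and Zfp958 had -2.64, with 41.6 and 5.83 CPM; both belong to large families whose members can share reads. Tbc1d8b followed at -2.05, Haus6, a subunit of the augmin complex, at -2.04, and Nap1l3 at -1.98. Myo10, an unconventional myosin, had -1.97 and Ormdl1, a regulator of sphingolipid synthesis, -1.94. Plcl1 at -1.93, the chemokine Cxcl12 at -1.80, Dsp at -1.71, Nudt16 at -1.67 and Tbc1d12 at -1.67 made up the rest. All 24 kept their direction in each of the 10 alternatives run for them. The mean CPM per nucleus could not have turned it, as the naming rule used it, and a smaller prior cannot turn a ratio. All alternatives used the same 2 libraries.

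Within classes, where fewer nuclei were pooled, more genes were at least 2-fold apart. There were 1059 higher and 1152 lower among 10367 genes in granule-like nuclei, 1468 and 1061 among 10621 in CA1-like nuclei, and 1864 and 2090 among 11053 in interneuron-like nuclei. Granule neuron markers had a median of -0.33 within granule-like nuclei, a smaller fall than the -0.78 of the whole library, and did not stand apart there. Class names did not exclude other RNA. An interneuron-like cluster of 33 nuclei was led by Apoe, Clu and Slc1a3 of astrocytes. Astrocyte markers had a median of -5.46 within interneuron-like nuclei, where granule neuron markers had -1.51 and ependymal markers -4.26. Within granule-like nuclei oligodendrocyte precursor markers had 2.55 and mature oligodendrocyte markers 2.5002, over 6 and 11 members. Within CA1-like nuclei subicular or entorhinal markers had -1.94 over 3 members. Each of these lists of other cell types stood apart.

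Among EdU+ nuclei the question was which cells had recently divided and how their transcripts differed. Nuclei with oligodendrocyte precursor genes were the main class in both genotypes. Under the naming rule they made up 86 of 167 or 51.5% in WT and 126 of 348 or 36.2% in Fasn-R1812W, held mostly by clusters 0 and 3 in WT and clusters 3 and 7 in Fasn-R1812W. With 2 further clusters that scored highest for the same markers but were left unnamed, the shares were 66.5% (58.8 to 73.6) and 57.8% (52.4 to 63.0), a difference of -8.71 points (-17.2 to 0.315). The relaxed filter gave -0.115 points for the named class, no filter 13.02, and 10 principal components on the same nuclei 3.46, so the direction differed between settings. Committed precursor-like nuclei made up 10.2% and 6.90%, neuroblast-like nuclei with Dcx and Igfbpl1 10.8% and 7.76%, astrocyte-like nuclei 7.19% and 6.03%, and the unnamed clusters 14.97% and 21.6%. The committed precursor-like difference of -3.28 points (-9.23 to 1.60) became -12.2 (-19.97 to -5.07) with 30 principal components and 0.119 in thinned nuclei. The neuroblast-like difference of -3.02 points (-9.12 to 2.05) kept its direction in 8 of 10 alternatives. It became 1.70 with 30 principal components and 0.418 without the 5% of nuclei with the most genes. The astrocyte-like difference of -1.15 points (-6.51 to 3.12) became -10.2 (-16.9 to -4.35) with 10 principal components and 1.89 by marker score. With wells thinned to 20000 reads, at least 3 astrocyte markers with at least 3 reads each were found in 24.5% of WT and 33.8% of Fasn-R1812W wells. The astrocyte-like cluster was led by Thrsp, Cdc7 and Top2a, the last 2 being genes of dividing cells. Thrsp is in the radial glia-like stem cell list, which scored second for this cluster, at 0.82 against 1.24 for astrocytes. Its leading genes held 1 marker from each list, so the name does not tell these 2 cell types apart.

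Immune nuclei were more frequent in the kept EdU+ Fasn-R1812W library. A leukocyte-gene cluster with S100a8, Lyz2, Ptprc, H2-Ab1, Ms4a4b, Ccl5 and Nkg7 among its leading genes held 6 of 167 WT nuclei or 3.59% (1.33 to 7.66). It held 43 of 348 Fasn-R1812W nuclei or 12.4% (9.09 to 16.3), a difference of 8.76 points (3.71 to 13.1). With no nucleus filter it held 26 and 49 of 384 wells, a difference of 5.99 points (1.79 to 10.3). Microglia-like nuclei made up 1.80% and 9.20% of kept nuclei, but 30 and 30 of 384 wells with no filter. By the same count in thinned wells, 9.14% and 13.8% held microglial markers, a difference of 4.69 points (0.101 to 9.30). That count was also higher for interneuron markers, by 8.15 points (3.31 to 13.004), for astrocyte markers, by 9.31 (2.80 to 15.7), and for oligodendrocyte precursor markers, by 7.61 (0.718 to 14.4). Lymphocyte markers were higher in 6 of 6 members with a median of 4.64 (3.43 relaxed), or 6.90 with the 4 members that had no WT read set at 3 reads. Ptprc, the common leukocyte antigen CD45, stood at 93.5 and 1121 CPM, or 267 and 1113 CPM over all wells. Perivascular macrophage markers had a median of 2.66 (3.74 at that limit), which became 0.93 under the relaxed filter. Microglial markers had a median of 1.55, which became 0.13. By the count in thinned wells, lymphocyte markers were found in 0 of 372 WT and 6 of 376 Fasn-R1812W wells, and perivascular macrophage markers in 1 and 3. Inflammation genes had a median of 1.14 (0.69 relaxed), with B2m at 543 and 2260 CPM, and -0.44 without leukocyte-gene and microglia-like nuclei.

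The 12 genes named as higher in EdU+ Fasn-R1812W nuclei had at least 1 read in 14.7% to 58.6% of its nuclei, but 10 or more reads in 3.16% to 8.62%. The naming rule counts any read, and 2149 genes were eligible as higher but 380 as lower. Whether low reads assigned from other wells let genes pass the 10% of that rule was not tested. Ms4a4b of T cells, on chromosome 19 at 11443553 to 11467055, stood at 0.1996 CPM (0.0412 to 0.583) from 3 reads in WT and at 595 CPM in Fasn-R1812W, where 5.75% of nuclei had 10 or more reads. Gimap4 and Klrd1, genes of lymphocytes and natural killer cells, had 0 reads in WT. Against the limit of 0.1996 CPM that 3 reads over the library give, they were at least 608-fold and at least 476-fold higher in Fasn-R1812W. Nkg7 and Ccl5 of cytotoxic lymphocytes had log2 ratios of 5.87 and 5.41, and 6.89 and 6.47 under the relaxed filter; their WT reads under the main filter came from 1 nucleus. Other genes had smaller ratios under that filter. Pycard, the inflammasome adaptor, went from 6.41 to 1.81, Rinl from 5.76 to 3.17, and Nckap1l from 5.31 to 0.80. Arhgap15 went from 4.97 to 1.45 and Arhgef3 from 4.91 to 1.04. Trim12a had 1 read in WT, at 0.0665 CPM, and 98.4 CPM in Fasn-R1812W, and Lrrk1 had 0 reads in WT and 36.2 CPM, which was at least 182-fold higher; their relaxed ratios were 1.23 and 1.11.

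Metabolic lists differed in the EdU+ comparison, and only part of that stayed under the relaxed filter. Cholesterol synthesis genes had a median of -0.60 (-0.62 relaxed) and were lower in 17 of 22 members. Srebf2, the transcription factor of the pathway, stood at 94.6 and 64.1 CPM. Within oligodendrocyte precursor-like nuclei the median was -0.95. Fatty acid synthesis genes had a median of -0.56 that came to 0.026 under the relaxed filter. Glycolytic genes had -0.70, lower in 16 of 19, with Tpi1 at 264 and 105 CPM; the relaxed median of -0.35 at percentile 3.59 no longer stood apart. Mitochondrially encoded transcripts were higher in 9 of 9 members with a median of 0.74 (1.08 relaxed), and mt-Nd4 stood at 424 and 977 CPM. They made up 0.33% of all reads in EdU+ WT and 0.63% in EdU+ Fasn-R1812W. Since nuclei were sorted and the source of these reads was not tested, they cannot be read as mitochondrial activity. Cytosolic ribosomal protein genes had a median of 0.62 (0.61 relaxed), higher in 21 of 22, and -0.094 without leukocyte-gene and microglia-like nuclei. Immediate early genes had -0.69 (-0.60 relaxed) with members on both sides, Jun at 48.8 and 19.4 CPM and Nr4a1 at 24.5 and 61.5 CPM. With the strict filter and its 5 WT nuclei the medians turned to 2.69 for cholesterol synthesis, 3.49 for immediate early genes and -0.61 for mitochondrially encoded transcripts.

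Some cell cycle and lineage lists of EdU+ nuclei had other medians under the relaxed filter. G2/M genes had a median of -0.54, and 0.30 under the relaxed filter. Genes of cell cycle exit had 0.54, and 0.48 relaxed, and did not stand apart under either filter. GABAergic synapse genes had -0.52, and -0.21 relaxed. Committed precursor markers were lower in 8 of 8 members at -0.65, and -0.22 relaxed. Fibroblast markers had -2.83 from 3 members, and -2.48 relaxed, and stood apart under both filters. Among the 29 gene lists, 9 stood apart and 5 of these also did so under the relaxed filter. Under the relaxed filter alone, lipid droplet genes (-0.94), nuclear genes of oxidative phosphorylation (-0.40) and G1/S genes (0.78) stood apart too. Among the marker lists, endothelial markers had 1.82, and 2.69 relaxed, and stood apart only under the relaxed filter. They were found in 0 of 372 WT and 2 of 376 Fasn-R1812W thinned wells.

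Single genes in EdU+ nuclei were uneven, with 1594 at least 2-fold higher and 740 lower in Fasn-R1812W among 9193 genes. The share of higher genes was 68.3%, 58.1% with no filter on low genes and 59.0% at a CPM of at least 50. The gene filter uses the share of nuclei with a read, and genes per nucleus differed between these libraries. The unevenness cannot be separated from that difference. Maneal, a mannosidase-like gene on chromosome 4 at 124855239 to 124862171, was lowest relative to WT, at 119 CPM (113 to 124) and 14.0 CPM (13.3 to 14.8), a log2 ratio of -2.99. Rps6kc1 followed at -2.92 and B4gat1, a glycosyltransferase of dystroglycan, at -2.59. Tm2d2 had -2.45, Fam110b -2.36 and the splicing factor Snrnp27 -2.28. Sphk2, a sphingosine kinase, had -2.26, and Selenos, a selenoprotein of the endoplasmic reticulum, -2.19. Ikzf4 at -2.15, Rnf10 at -2.13, Nell2 at -1.98 and Tmem60 at -1.98 completed the set. All 12 were also lower under the relaxed filter, with ratios from -3.66 for B4gat1 to -0.78 for Tmem60. With the strict filter, which left 5 EdU+ WT nuclei, 8 of the 12 were higher.

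**Figure D3:**
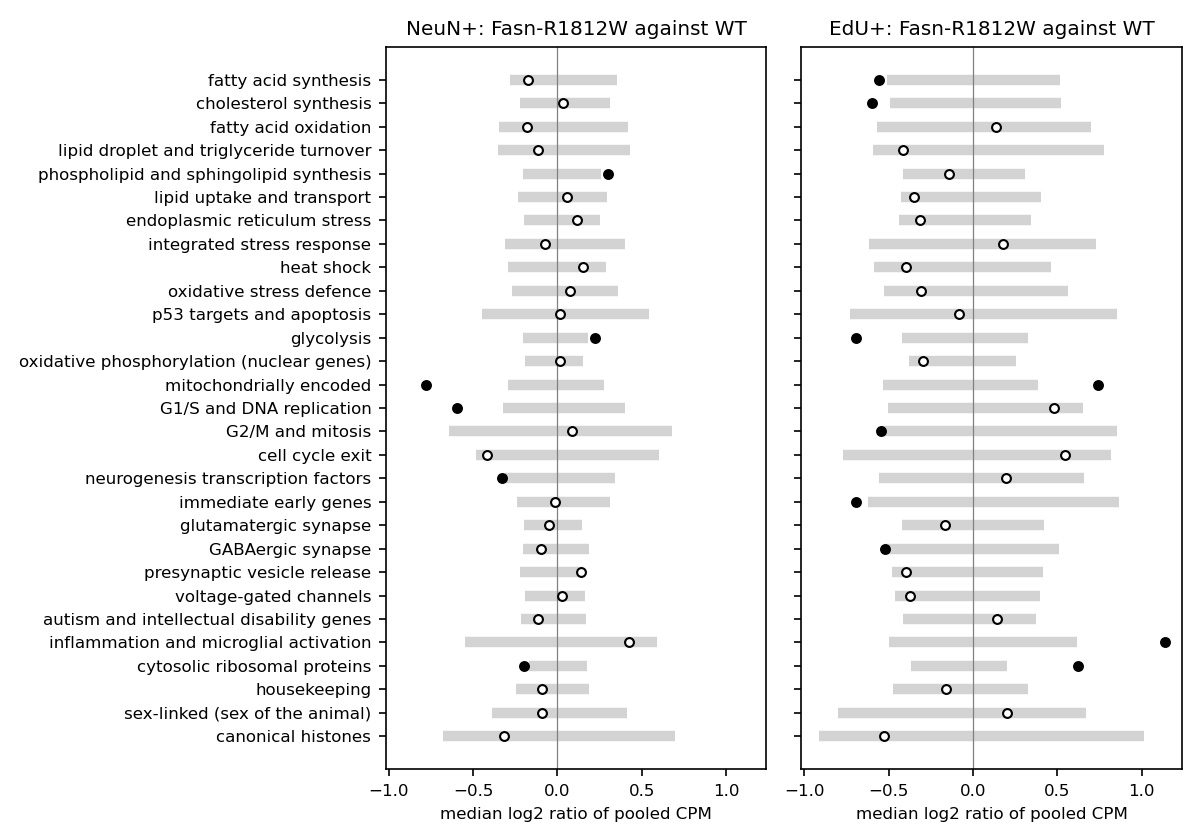
Points are median log2 ratios of pooled CPM, Fasn-R1812W over WT, for the 29 gene lists in NeuN+ and EdU+ nuclei, and grey bars span the middle 95% of 10000 matched random lists. Filled points lie outside the bars, such as mitochondrially encoded transcripts at -0.78 in NeuN+ and 0.74 in EdU+ nuclei.

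Genotype ratios of the 2 gates showed little correlation across genes. Pearson's r was -0.038 and Spearman's rho -0.066 over 10670 genes, which are not independent replicates, and the 2 comparisons share no library.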

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

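The tests of index sharing, equal depth, markers per well, blood genes, glial markers and granule markers within a class were chosen after the results were seen; the settings with no nucleus filter and with thinned nuclei had been fixed beforehand but were read as tests afterwards. Among the gene lists that stood apart in both gates, 3 had opposite directions, a difference that was not tested because each group has 1 library. Glycolysis had a median log2 ratio of 0.22 in NeuN+ and -0.70 in EdU+ nuclei. Mitochondrially encoded transcripts had -0.78 and 0.74, from reads whose source in sorted nuclei was not tested. Cytosolic ribosomal proteins had -0.20 and 0.62, but EdU+ nuclei had -0.094 without leukocyte-gene and microglia-like nuclei and -0.11 within precursor-like nuclei, no longer opposite to NeuN+. EdU+ glycolysis had -0.35 under the relaxed filter and no longer stood apart. In data outside the comparisons, 27 microglia-like EdU+ WT nuclei were found among the wells that the nucleus filter left out.

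EdU+ Fasn-R1812W wells had more genes with a read than EdU+ WT wells, by a ratio of medians of 3.02. Depth alone was argued against as the whole cause for genes with a read, since the ratio was 1.60 with wells thinned to 20000 reads. That left out 12 EdU+ WT and 8 EdU+ Fasn-R1812W wells with fewer reads. However, genes with at least 3 reads had a ratio of 1.35 in the thinned wells. Kept nuclei thinned to 69000 reads had 1.48 for genes with a read and 1.05 for genes with at least 3. Reads assigned to wells that share an index with the true well may contribute: for genes with at least 500 reads in 1 well only, wells sharing 1 index with it held 1 to 9 reads 4.41 times as often as wells sharing none, against 1.17, 1.05 and 0.93 in the other libraries. Genotype cannot be told apart from the library, as there was no second library of either genotype. Such spill leaves the pooled CPM over all wells of a library as it was, but alters genes per well and therefore which nuclei are kept. It also alters the share of nuclei with a read, which the gene filter and the naming rule use.

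Immune nuclei took a larger share of kept EdU+ Fasn-R1812W than EdU+ WT nuclei. For microglia-like nuclei the nucleus filter cannot be told apart from other causes, since the difference was 0 points (-3.87 to 3.87) with no nucleus filter and 4.69 points (0.101 to 9.30) in wells holding microglial markers at 20000 reads, intervals that overlap, and wells with interneuron, astrocyte or oligodendrocyte precursor markers were also more frequent, by 8.15, 9.31 and 7.61 points. For the leukocyte-gene cluster the filter was argued against as the whole cause, with a difference of 5.99 points left. More blood in the tissue could not be decided. The median log2 ratio of 8 neutrophil genes over all wells was -0.28, while 6 lymphocyte markers had 3.42. The neutrophil genes were split, with 5 below and 3 above 0, from -1.16 to 0.80. Such a split does not settle where the lymphocyte genes came from. The most abundant neutrophil gene, S100a8, stood at 835 and 784 CPM over all wells, and red blood cell genes were lower in 4 of 4, at -3.10. Genotype and the animal sampled cannot be told apart with 1 library each and remain open for the 8.76 points.

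Granule neuron-like nuclei took a smaller share of NeuN+ Fasn-R1812W nuclei. Depth per nucleus was argued against, since the difference stayed at -12.4 points in thinned nuclei. Nuclei that met the glial marker cut were argued against as the cause, since the difference was -17.2 points without them. They were 46 of 314 WT and 41 of 301 Fasn-R1812W nuclei, and the classes stayed as clustered with them. Glial RNA below the cut, or its part in the clustering, was therefore not tested. A different part of the hippocampus sampled, or fewer granule neurons in the mutant animal, could each give the pattern. Granule markers had a median of -0.33 within granule-like nuclei, which both allow, so these cannot be told apart with 1 library per genotype.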

How the results depend on the processing

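No paired analysis was possible because each group had 1 library. The relaxed filter, the setting of low counts to 0 and the removal of immune or glial-marker nuclei were chosen after seeing the data; all others were planned. In NeuN+ nuclei the medians of the lists that stood apart and the 24 named genes kept their direction in the alternatives run for them. For the named genes, the mean CPM per nucleus and the smaller prior could not have turned it. Granule-like and CA1-like share differences kept their direction in 13 of 13 alternatives, from -17.4 to -6.70 and from 2.60 to 10.02 points. The CA1-like interval held 0 in 5 of these. Leiden resolution 0.5 gave no leukocyte-gene cluster. In the other alternatives the leukocyte-gene difference was positive in 11 of 11, from 4.71 to 9.63. The lowest came from the strict filter, with 0 of 5 WT and 14 of 297 Fasn-R1812W nuclei (-38.8 to 7.76). With no WT nucleus in the cluster that difference could not be negative. The correlation between gates moved by at most 0.1 in every setting run. The cause of each change below was not tested, with these exceptions. The strict filter left 5 EdU+ WT nuclei, gene filters alter how many genes are counted, and resolution 0.5 gave no leukocyte-gene cluster.

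Counts of genes at least 2-fold higher and lower in NeuN+ were 211 and 190 with the mean CPM per nucleus, 223 and 193 in thinned nuclei, 1298 and 1329 with no filter on low genes, 90 and 96 at a CPM of at least 50, and 182 and 190 with the relaxed filter and counts under 10 set to 0. In EdU+ they were 5710 and 2558 with the strict filter, 3930 and 2836 with no filter on low genes, and 243 and 133 with the relaxed filter and counts under 10 set to 0. In thinned EdU+ nuclei 1044 were higher and 528 lower, and at a CPM of at least 50 the counts were 945 and 658.

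The strict filter turned EdU+ list medians to 3.57 for fatty acid synthesis, 2.69 for cholesterol synthesis, -0.61 for mitochondrially encoded, 3.49 for immediate early, 0.013 for GABAergic synapse, -0.69 for ribosomal protein and 3.95 for committed precursor genes. It turned Rps6kc1 to 3.58, B4gat1 to 3.62, Tm2d2 to 0.37, Fam110b to 3.03, Selenos to 3.44, Ikzf4 to 2.44, Rnf10 to 1.53 and Tmem60 to 5.59. The median of G2/M genes was 0.35 with no nucleus filter, 0.30 with the relaxed filter and 0.25 with low counts also set to 0. Microglial markers had -0.086 with no nucleus filter. Fatty acid synthesis had 0.026 with the relaxed filter, and GABAergic synapse genes 0.0017 with low counts also set to 0. Without immune nuclei, inflammation genes had -0.44 and ribosomal protein genes -0.094.

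Differences in share, in points, also moved. Granule-like nuclei had -6.70 with the strict filter, CA1-like 2.60 with no nucleus filter and CA3-like -0.0984 by marker score. The precursor-like class of EdU+ nuclei had 7.27 with the strict filter, 13.02 with none, -0.115 relaxed, 0.937 relaxed with low counts set to 0, and 1.33 with low counts set to 0 in kept nuclei. It had -0.678 and -3.32 at Leiden resolutions of 0.5 and 2, 3.46 and 0.587 with 10 and 30 principal components, and -3.63 by marker score. Microglia-like nuclei had -3.16 with the strict filter, 0 with none, 0.308 relaxed, -0.0184 relaxed with low counts set to 0, and 16.2 at resolution 0.5. At that resolution the leukocyte-gene cluster had 0 nuclei in either library, and the microglia-like class held 9 WT and 75 Fasn-R1812W nuclei. In the main setting the microglia-like class held 3 and 32 and the leukocyte-gene cluster 6 and 43. The 16.2 points are therefore not a value for microglia-like nuclei alone. Kept nuclei held 15088319 reads in EdU+ WT and 95434447 in EdU+ Fasn-R1812W, where 199 and 0 wells had under 1000 genes and 60 and 36 had under 50000 reads.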

Other observations

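Within oligodendrocyte precursor-like EdU+ nuclei, spread over the same 4 clusters in different proportions in the 2 libraries, 1945 genes were at least 2-fold higher and 1416 lower among 8678. Genes of endoplasmic reticulum stress had a median log2 ratio of -0.63 and those of the integrated stress response 1.03, and both stood apart from matched random lists. So did markers of another cell type, CA3 pyramidal neurons, at -2.69 over 5 members. Glycolytic genes had -0.69 there and mitochondrially encoded transcripts 0.67, close to the values of the whole gate. Ribosomal protein genes had -0.11 there, against 0.62 in the whole gate. Within interneuron-like NeuN+ nuclei, lipid uptake genes had a median of -0.54, in a class whose astrocyte markers also differed.

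The position of the lowest wells was looked at after the depths were seen. The well with index pair N729_S511 and the well with N729_S522 were among the 6 with the fewest reads in each library. In EdU+ Fasn-R1812W these wells held 1858 and 3928 reads over 1278 and 2350 genes, and in EdU+ WT 21 and 144 reads over 21 and 18 genes. They held 643 and 1456 reads over 519 and 1113 genes in NeuN+ WT, and 317 and 844 reads over 291 and 732 genes in NeuN+ Fasn-R1812W. No label says whether these wells held a nucleus.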
